A study of Mus musculus with 11 samples.

How the data were processed

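Bone-marrow cells of Rag1-/- C57BL/6 mice aged 7 weeks were grown in culture over 7 days, and cells carrying F4/80, a surface protein of mouse macrophages, were then sorted, per the labels' protocols. M0 cells received no cytokines (5 arrays), M1 cells received interferon-gamma and lipopolysaccharide (3 arrays) and M2a cells received IL-4 and IL-13 (3 arrays). Total RNA of each sample was hybridized to an Affymetrix mouse genome array. The labels number the replicates of each group and do not say whether they came from separate mice, so p-values measure only the spread between these samples, which may be technical.

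The authors deposited log2 values for 45101 probe sets per array. Partek is named, without a version, in the submitters' processing notes; the background correction, the summary of probes and the normalization are not given in the sources used here. The values ran from 0.73 to 14.49, and the array medians lay between 5.14 and 5.34. The number of arrays limits the precision. In the deposited log2 values, the mean of M0 arrays 1 to 3 equalled the mean of M0 arrays 4 and 5 on all 45101 probe sets, with a largest difference of 8.3e-05, while the other 9 ways of parting 2 M0 arrays from 3 gave median differences of 0.0874 to 0.31. The deviations of the 11 arrays therefore have 9 independent directions in place of 10, and the 5 M0 arrays carry less information on their own spread than 5 independent arrays. No source used here gives the reason. The 8 residual degrees of freedom of the fit count the M0 arrays as independent.

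A table of probe sets and genes listed 35890 of the probe sets. Of these, 34945 had 1 gene symbol, of which 34741 were brought up to date through the Entrez identifier, and 932 had several symbols and were left out. The other 9211 probe sets are not in that table; 9160 of them are not control probe sets and were tested only for the closing section. The 64 control probe sets of the array were left out of the tests of genes. Each of the 18193 genes was represented by its probe set with the highest mean over the 11 arrays, chosen without regard to group; 9010 genes had several probe sets. No column of the table was left out and no filter on low values was used.

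Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean per group, all 11 arrays in one fit), with Benjamini-Hochberg adjustment over the 18193 genes and a threshold of 0.05. Errors of differences are standard errors (SE) of that fit. The count of genes changed at least 2-fold is given beside, since the series' design text names that threshold against M0. The deposited values are already on a log2 scale, so the planned transformation of linear values did not apply. For 28 gene lists, of which 533 of 592 genes were measured, limma's camera was run with a preset correlation between genes of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. The gene lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 8 largest rises and the 8 largest falls against M0 (5 and 5 for M1 against M2a) among called genes whose arrays do not overlap between the groups, up to 2 rises and 2 falls per list in each comparison against M0, and 20 marker genes in every comparison, and it passed over clone-like symbols.

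The test was checked on simulated data for the 18193 genes, with 100 genes changed 2-fold and 100 changed 4-fold per comparison. With an equal spread in all groups, 85% of the genes changed 2-fold and 98% of those changed 4-fold were recovered in M1 against M0, and 5% of the calls were unchanged genes; in M2a against M0 these values were 87%, 99% and 6.06%. With the spread scaled by group and no tie, 11 unchanged genes, 4.955% of 222 calls, were called in M1 against M0 and 5, 2.59% of 193 calls, in M2a against M0. With the spread scaled by group and the M0 means tied as in the deposited values, 213 unchanged genes, 49.4% of 431 calls, were called in M1 against M0 and 200, 51.2% of 391 calls, in M2a against M0. With the measured spread of each gene and group these numbers were 292 (57.9% of 504 calls) and 291 (60.6% of 480 calls). The simulations with tied means were added after the tie had been seen. Fits with a term for 2 runs, the M0 arrays 1 to 3 and the M0 arrays 4 and 5, were added for the same reason, with M1 and M2a placed in either run, since the sources used here do not give their run.

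The alternatives were other normalizations, other ways to choose a probe set, filters on low values, eBayes with trend and robust settings, fits of fewer arrays, array weights, the replicate number as a block, each array left out in turn, control-probe covariates and the run term. For genes changed in both comparisons against M0, unchanged groups were simulated 50 times around the M0 means, with the M0 arrays drawn anew as well. The measured M0 arrays were also split in 20 ways. Because of the tie, the parts are not fully independent.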

Results

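Macrophages grown from mouse bone marrow were profiled in 3 states: M0, without cytokines (5 arrays); M1, with interferon-gamma and, for the last 24 h, lipopolysaccharide (3 arrays); and M2a, with IL-4 and IL-13 (3 arrays). The series used M0 as the common standard, so each cytokine state was compared with M0 and the 2 states with each other. Values are deposited log2 probe-set values, given as mean ± SD. Correlations between arrays across genes were 0.956 to 0.995 within M0, 0.997 to 0.998 within M1 and 0.996 to 0.998 within M2a. The median SD of a gene was 0.24 in M0, 0.08 in M1 and 0.09 in M2a. The first principal component held 50.3% of the variance and the second 33.9%. The M0 arrays 1 to 3 and the M0 arrays 4 and 5 had the same mean on every probe set within 8.3e-05, so the M0 arrays are not 5 independent measurements.

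The comparison of M1 with M0 asks what interferon-gamma and lipopolysaccharide changed, and its rises included many interferon-induced genes. Cxcl9, a chemokine induced by interferon-gamma, rose from 2.73 ± 0.14 (SD, n = 5) in M0 to 12.21 ± 0.12 (SD, n = 3) in M1. The difference was 9.48 ± 0.10 (SE) with an adjusted p of 1.7e-13 in limma. Saa3, an acute-phase protein, rose by 8.06, Cfb, complement factor B, by 7.93, Ccl5 by 7.63, Gbp2 by 7.57, Ly6i by 7.55, Ubd by 6.83 and the scavenger receptor Marco by 6.77. All of these passed the limma test. In the limma fit 7217 of 18193 genes changed, 4022 upward and 3195 downward, and 2306 of them changed at least 2-fold (1140 higher, 1166 lower). The balance of the 2-fold changes was 706 higher and 1311 lower with the actin 5'-3' difference as a covariate, 1001 and 2111 with the hybridization controls as a covariate, and 802 and 1176 without M0 arrays 1 and 4, settings chosen after the data were seen. The median over all genes was 0.06.

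Of the 23 measured M1 markers, 21 rose and none fell, also when adjusted over the list alone (median 2.64, camera adjusted p = 5.4e-16). Il1b rose by 4.15, Il6 by 3.31, Tnf by 2.64, Nos2, the inducible nitric oxide synthase, by 2.24, Il12b by 1.52 and Cd86 by 1.00. Il12b stayed low, at 3.74 to 4.16 in M0 and 5.24 to 5.57 in M1, under the median gene of M0 at 5.97. Of 27 type I interferon response genes, 26 rose (26 adjusted over the list alone), among them Ifit1 by 5.75 and Ifit2 by 4.83 (for the list, adjusted p = 4.9e-19, and adjusted p = 0.062 with an estimated correlation). All 11 interferon-gamma GTPases rose (11 adjusted over the list alone), Gbp3 by 6.20 (for the list, adjusted p = 1.6e-12). All 16 MHC class I genes rose (16 adjusted over the list alone), Tap1, a peptide transporter, by 3.22 and Nlrc5 by 3.38 (for the list, adjusted p = 2.5e-12, and adjusted p = 0.060 with an estimated correlation). Of 10 MHC class II genes, 9 rose (9, with 1 lower, adjusted over the list alone), Cd74 by 5.05 and H2-Eb1 by 4.55 (for the list, adjusted p = 6.6e-08). The M1 marker, interferon-gamma GTPase and MHC class II calls held with an estimated correlation.

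Of 33 genes of TLR and NF-kB signalling, 21 rose and 2 fell (23 and 3 adjusted over the list alone), with Nfkbie up by 2.83 (for the list, adjusted p = 4.1e-06, and adjusted p = 0.15 with an estimated correlation). Of 28 cytokines, 16 rose and 5 fell (16 and 6 adjusted over the list alone). Il1a rose by 3.42 and Il16 fell by 3.47 (for the list, adjusted p = 0.012, and adjusted p = 0.099 with an estimated correlation). That call was lost in 3 of 30 alternatives, among them genes above the median gene (adjusted p = 0.54) and M0 arrays 1 to 3 only (adjusted p = 0.056). Il10, an anti-inflammatory cytokine, rose by 2.48. The chemokine list moved both ways, with 9 higher and 7 lower of 27, the same counts adjusted over the list alone (adjusted p = 0.75). Of 19 glycolysis genes, 14 rose and 1 fell, the same counts adjusted over the list alone. Pfkfb3, which drives glycolysis, rose by 3.23 and the glucose transporter Slc2a3 fell by 4.90 (for the list, adjusted p = 2.8e-05, and adjusted p = 0.060 with an estimated correlation). Without _x_at and _s_at probe sets, Slc2a3 fell by 0.37. Of 20 cholesterol synthesis genes, 9 fell and none rose, also adjusted over the list alone (adjusted p = 0.0020, and adjusted p = 0.59 with an estimated correlation). Of 36 genes of the TCA cycle and respiratory chain, 16 rose and 4 fell (20 and 4 adjusted over the list alone; adjusted p = 0.023, and adjusted p = 0.80 with an estimated correlation). That call was lost in 6 of 30 alternatives, among them without M0 array 1 (adjusted p = 0.062) and without M0 array 4 (adjusted p = 0.060), and its direction reversed in 2 more, with either control-probe covariate.

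The M2a marker list fell in M1, with 7 higher and 13 lower of 29, the same counts adjusted over the list alone (median -0.26, adjusted p = 0.040, and adjusted p = 0.33 with an estimated correlation). That call was lost in 7 of 30 alternatives, among them without M0 array 1 and without M0 array 5 (adjusted p = 0.062 in both). Chil3, a chitinase-like protein, fell by 5.22, Alox15 by 5.21 and Mrc1, the mannose receptor, by 4.85. Arg1, arginase 1, instead rose by 3.48 and Slc7a2, an arginine transporter, by 5.19. Chil3 is also in the monocyte list. Within M0, Chil3 (13.44) and Alox15 (10.03), but not Mrc1, were highest in array 1, as were 11 of 13 neutrophil-lineage genes. Whether other cells in the M0 sort bear on the M0 levels of Chil3 and Alox15 was not tested. Hmox1, heme oxygenase 1, rose by 3.53. Of 33 cell cycle genes, 28 fell and 2 rose, the same counts adjusted over the list alone (adjusted p = 5.5e-16, and adjusted p = 0.14 with an estimated correlation). Mki67 fell by 2.46 and Rrm2 by 4.81, while Ccne1 rose by 1.57.

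The largest falls in M1 included granulocyte and eosinophil genes. Mpo, the myeloperoxidase of neutrophil precursors, fell from 11.57 ± 1.08 (SD, n = 5) to 3.97 ± 0.17 (SD, n = 3), Prg2, an eosinophil granule protein, fell by 6.86 and Ltf, lactoferrin, by 6.53. Of 13 neutrophil-lineage genes, 12 fell (12 adjusted over the list alone; adjusted p = 2.7e-12, and adjusted p = 0.062 with an estimated correlation). Of 16 mast cell, basophil and eosinophil genes, 12 fell and 2 rose, the same counts adjusted over the list alone (adjusted p = 4.6e-06, and adjusted p = 0.24 with an estimated correlation). Myb fell by 6.20, Serpinb2 by 6.44, Hpgd by 6.43, Ppbp by 6.10 and Xist, the RNA of the inactive X chromosome, by 6.24. Without _x_at and _s_at probe sets, which can bind several transcripts, Hpgd fell by 1.44 and Rrm2 fell by 1.65. With the mean of a gene's probe sets, Cxcl9 rose by 5.67, Tap1 by 1.22 and Cd86 by 2.45, and Il16 fell by 1.30. With the hybridization controls as a covariate, Nos2 rose by 3.58, Hmox1 by 1.97 and Nlrc5 by 1.76, Mki67 fell by 1.54, and the calls of Cd86 (0.016), of the TLR and NF-kB list (adjusted p = 0.096), of glycolysis (adjusted p = 0.068) and of the M2a markers (adjusted p = 0.31) were lost. With a term for 2 runs of M0 arrays, M1 and M2a placed with M0 arrays 4 and 5, 4389 genes changed in M1 against M0. The tie of the M0 means sets that term to 0, so no difference moves, the lower count comes from fewer degrees of freedom and fewer M0 arrays beside M1, and the fit does not test for run differences. In 2 simulations with M0 means tied in the same way, 213 and 292 unchanged genes among the 18193 were called in M1 against M0. They made up 49.4% and 57.9% of the calls there. Far fewer genes were changed in the simulations than were called in the data. The simulated counts and shares therefore do not give the number of false calls in the data. The spiked poly-A controls, which no cell contains, averaged 9.62 ± 0.50 in M0 and 5.62 ± 0.05 in M1. The 5' minus 3' difference of the actin control probe sets was -0.61 ± 0.47 in M0 and 0.15 ± 0.02 in M1, that of Gapdh was -0.37 ± 0.60 and 0.57 ± 0.03, and the mean of the 18S ribosomal RNA probe sets was 9.25 ± 0.27 and 6.25 ± 0.08.

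**Figure D1:**
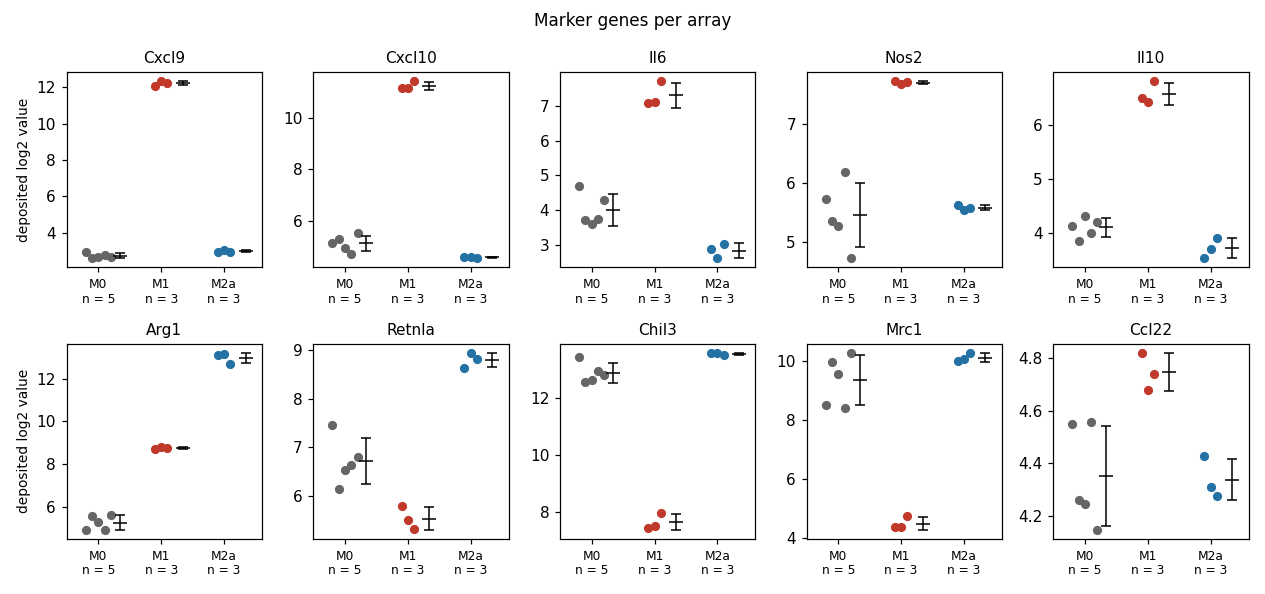
Deposited log2 values (vertical axis) of 10 marker genes in each array, by group (horizontal axis: M0, n = 5; M1, n = 3; M2a, n = 3). Points are arrays and black bars are mean ± SD; Cxcl9 averaged 12.21 in M1 and 2.73 in M0, and Arg1 averaged 12.97 in M2a and 5.29 in M0.

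M2a macrophages had their highest rise over M0 among the named genes in Arg1, which went from 5.29 ± 0.33 (SD, n = 5) to 12.97 ± 0.25 (SD, n = 3). The difference was 7.68 ± 0.18 (SE) with a limma adjusted p of 3.6e-10. Serpinb9b rose by 5.81, the ribonuclease gene Rnase2a by 5.64, the lectin Mgl2 by 5.52, the collagenase Mmp13 by 5.44, Itgax, which encodes CD11c, by 4.86 and Tmem267 by 4.78. Y-linked Eif2s3y rose by 6.11. In the limma fit 5804 of 18193 genes changed, 3380 upward and 2424 downward, and 1703 of them changed at least 2-fold (802 higher, 901 lower). The balance was 707 higher and 1998 lower with the hybridization controls as a covariate, and 560 and 944 without M0 arrays 1 and 4. The median over all genes was 0.07.

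Of 29 measured M2a markers, 16 rose and 3 fell (17 and 5 adjusted over the list alone; median 0.77, adjusted p = 0.00014, and adjusted p = 0.10 with an estimated correlation). Retnla, a secreted M2 marker, rose by 2.09 and Chil3 by 0.67, while F13a1, a coagulation factor subunit, fell by 6.57 and Alox15 by 3.60. The call of Chil3 was lost in 8 of 30 alternatives, among them without M2a array 1, 2 or 3 (adjusted p = 0.065, 0.064 and 0.052). Its difference ranged from 0.592 to 1.365 over the alternatives. Several usual M2a genes did not pass the test in the limma fit. Mrc1 differed by 0.77 ± 0.38 (SE; adjusted p = 0.15), Ccl17 by -0.05 ± 0.12 (adjusted p = 0.79), Ccl22 by -0.01 ± 0.11 (adjusted p = 0.94) and Ccl24 by 0.30 ± 0.12 (adjusted p = 0.077). Ccl17 lay at 4.71 to 5.29 and Ccl22 at 4.15 to 4.82 in all arrays, under the median gene of M0 at 5.97. Their probe sets may lack signal, so these 2 values do not show that the genes did not respond. With the hybridization controls as a covariate, chosen after the data were seen, Mrc1 was -1.32 and Ccl22 0.45, and both passed. Mrc1 passed as a rise in 4 of 30 alternatives, among them without M0 array 5 (1.01, adjusted p = 0.031). Ccl24 passed in 6 of 30, among them without M0 array 1 (0.37, adjusted p = 0.022), without M0 arrays 1 and 4 (0.41, adjusted p = 0.0063), with array weights (0.39) and with the hybridization covariate (0.62, adjusted p = 0.022).

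Of 23 M1 markers, 2 rose and 11 fell (3 and 11 adjusted over the list alone; adjusted p = 0.00026). Fpr2, a formyl peptide receptor, fell by 5.66, Ptgs2 fell by 3.18, Il1b by 1.76, Cd86 by 1.41 and Il6 by 1.18, while Tnf differed by -0.08 ± 0.11 (adjusted p = 0.60). Of 27 chemokines, 3 rose and 12 fell (6 and 12 adjusted over the list alone), Cxcl3 by 4.65 (for the list, adjusted p = 0.00074). Of 28 cytokines, 2 rose and 13 fell (4 and 13 adjusted over the list alone), with Ebi3 lower by a log2 difference of -3.53 (for the list, adjusted p = 0.00023). These 3 calls held with an estimated correlation. Of 10 MHC class II genes, 5 fell and none rose, also adjusted over the list alone (adjusted p = 0.014, and adjusted p = 0.20 with an estimated correlation), a call lost without _x_at and _s_at probe sets (adjusted p = 0.055). In TLR and NF-kB signalling, 13 of 33 genes fell and 7 rose (13 and 8 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.52 with an estimated correlation).

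Of 36 genes of the TCA cycle and respiratory chain, 24 rose and 1 fell (25 and 1 adjusted over the list alone), Sdhc by 1.28 and Cyc1 by 0.87 (for the list, adjusted p = 4.7e-06, and adjusted p = 0.52 with an estimated correlation). The median of that list, 0.52, was -0.09 with the hybridization controls as a covariate. Of 24 matrix remodelling genes and growth factors, 15 rose and 8 fell (15 and 9 adjusted over the list alone; adjusted p = 0.36). Ctsk, a collagen-degrading cathepsin, rose by 3.87, while Serpinb2 fell by 5.53. Of 23 scavenger, efferocytosis and complement genes, 4 rose and 12 fell (6 and 13 adjusted over the list alone; adjusted p = 0.0034, and adjusted p = 0.52 with an estimated correlation). The scavenger receptor Stab1 fell by 4.29 and Axl by 4.11. Of 19 macrophage identity genes, 4 rose and 9 fell (5 and 10 adjusted over the list alone; adjusted p = 0.0017, and adjusted p = 0.52 with an estimated correlation). Csf1r fell by 1.21, Aif1 by 4.74 and Maf by 3.94. The iron exporter Slc40a1 fell by 5.07. Of 21 oxidative stress and iron genes, 8 fell and 2 rose, the same counts adjusted over the list alone (adjusted p = 0.0036, and adjusted p = 0.52 with an estimated correlation). Of 27 type I interferon genes, 9 fell and 3 rose (10 and 3 adjusted over the list alone; adjusted p = 0.027, and adjusted p = 0.63 with an estimated correlation), and of 20 cholesterol synthesis genes, 5 fell and 1 rose, the same counts adjusted over the list alone (adjusted p = 0.028, and adjusted p = 0.63 with an estimated correlation). The first call was lost in 5 and the second in 6 of 30 alternatives; both were lost without M2a array 3 (adjusted p = 0.098 and 0.14) and without M0 array 2 (0.073 and 0.061) or 5 (0.099 in both), and that of cholesterol synthesis also without M0 array 3 (0.054).

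All 13 neutrophil-lineage genes fell, also adjusted over the list alone (median -6.44, adjusted p = 1.4e-19). S100a9 fell from 14.11 ± 0.18 (SD, n = 5) to 4.75 ± 0.64 (SD, n = 3), Ngp by 8.44, Lcn2 by 8.42, Mpo by 6.81 and Prtn3 by 6.75. Prg2 fell by 8.61 and the monocyte gene Plac8 by 7.23. Of 33 cell cycle genes, 28 fell and 1 rose, the same counts adjusted over the list alone (adjusted p = 1.4e-19, and adjusted p = 0.14 with an estimated correlation). Mki67 fell by 3.59. Of 16 mast cell, basophil and eosinophil genes, 11 fell and none rose (11 and 1 adjusted over the list alone; adjusted p = 5.1e-06, and adjusted p = 0.27 with an estimated correlation). Of 8 monocyte genes, 5 fell and 2 rose, of 15 stroma and endothelium genes, 8 fell and 1 rose, and of 11 erythroid and megakaryocyte genes, 4 fell and none rose, the same counts adjusted over the list alone (adjusted p = 0.0032, 0.00050 and 0.018, and adjusted p = 0.52, 0.20 and 0.52 with an estimated correlation). With the run term, which is 0 here too, and M2a placed with M0 arrays 4 and 5, 3256 genes changed in M2a against M0. In the 2 simulations with tied M0 means, 200 and 291 unchanged genes among the 18193 were called in M2a against M0. They made up 51.2% and 60.6% of the calls there, and again do not give the number of false calls in the data. With the hybridization covariate, Mmp13 rose by 2.46 and Ctsk by 1.86, and the calls of Sdhc (0.20), Cyc1 (0.23), Il6 (-0.83), the M1 markers (adjusted p = 0.0504), the chemokines (adjusted p = 0.058) and the lists of mast cells, monocytes, stroma and erythroid cells (adjusted p = 0.091, 0.17, 0.054 and 0.83) were lost. With the mean of a gene's probe sets, Axl fell by 1.94, Ptgs2 fell by 2.05 and Eif2s3y rose by 3.23. The actin 5' minus 3' difference was -0.57 ± 0.06 in M2a, that of Gapdh -0.30 ± 0.04 and the 18S mean 8.56 ± 0.07. The poly-A controls averaged 6.40 ± 0.10 in M2a, and Xist, which averaged 5.69 in M2a arrays 1 and 2, was 5.31 higher in M2a array 3.

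**Figure D2:**
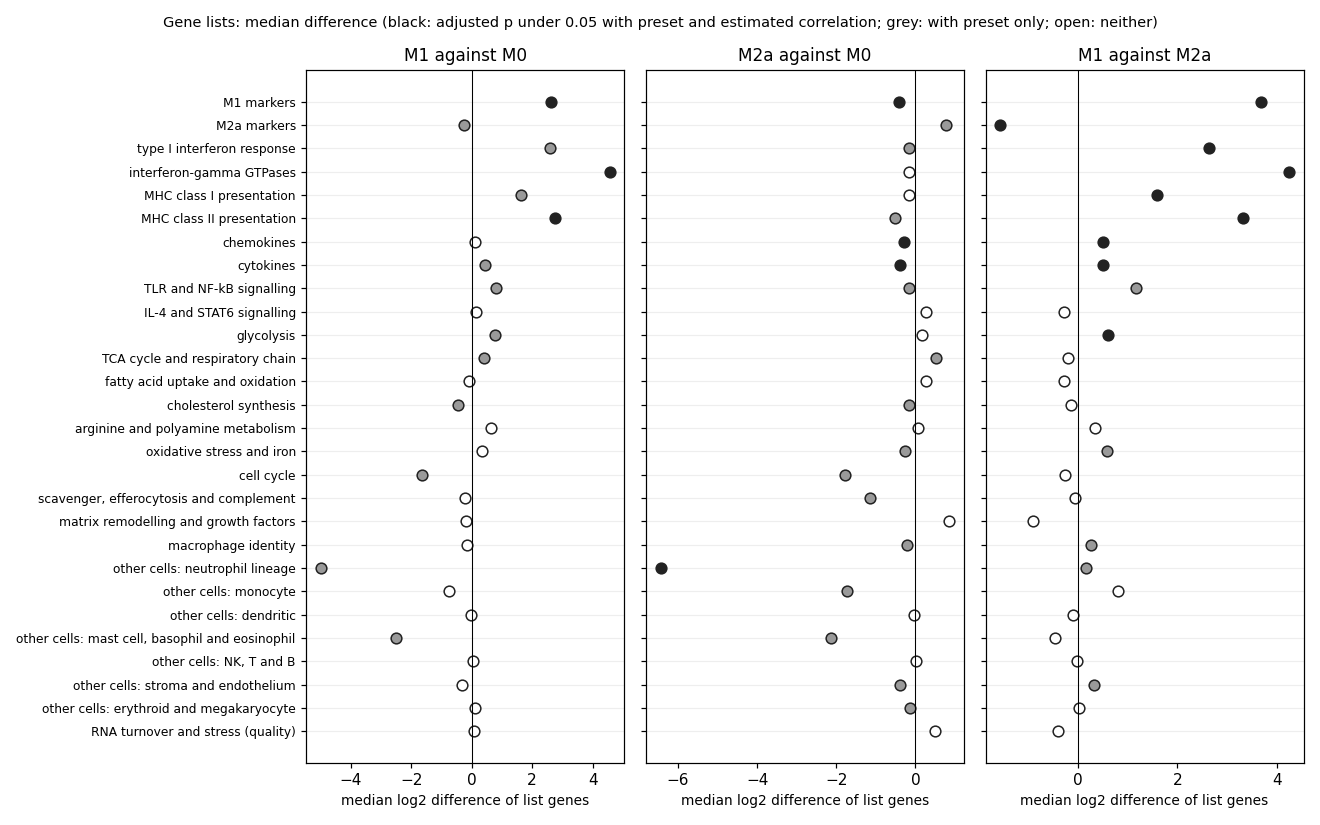
Median log2 difference (horizontal axis) of the measured genes of each of 28 gene lists (vertical axis) in the 3 comparisons. Black points passed an adjusted p of 0.05 with a preset and with an estimated correlation, grey points only with the preset one and open points with neither; the interferon-gamma GTPases lay at 4.57 in M1 against M0 and the neutrophil list at -6.44 in M2a against M0.

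In the direct comparison of M1 with M2a, 5341 genes changed in the limma fit, 2500 higher in M1 and 2841 higher in M2a, and 1998 changed at least 2-fold (1002 and 996, but 803 and 1459 with the actin covariate). Cxcl9 was higher in M1 by 9.22, Lcn2 by 8.62, Marco by 8.56, Ptgs2 by 8.50 and Ms4a6b by 8.44. Genes higher in M2a, given as M1 minus M2a, included Bex1 at -10.23, Atp6v0d2, a subunit of the vacuolar proton pump, at -7.35, Mgl2 at -6.96, Anxa1 at -6.62 and Itgax at -6.15. All of these passed the test. Over the alternatives, Cxcl9 was higher in M1 by 5.57 to 9.30, and Anxa1 lay at -6.87 to -4.40.

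Of 23 M1 markers, 20 were higher in M1 and none lower, and of 29 M2a markers, 19 were lower and 5 higher (20 and none, and 20 and 5, adjusted over the list alone; adjusted p = 1.1e-22 and 2.4e-07). Il1b was higher in M1 by 5.92, Il6 by 4.49, Il10 by 2.87, Tnf by 2.72 and Nos2 by 2.11, while Arg1 was lower by a log2 difference of -4.20, Chil3 of -5.89, Mrc1 of -5.62 and Retnla of -3.28. All 27 type I interferon genes, 11 interferon-gamma GTPases and 16 MHC class I genes were higher in M1, as were 8 of 10 MHC class II genes, the same counts adjusted over the list alone (adjusted p = 5.4e-26, 1.6e-15, 1.6e-15 and 7.9e-11). These calls held with an estimated correlation. Of 27 chemokines, 14 were higher and 5 lower, of 28 cytokines, 15 and 2, and of 19 glycolysis genes, 12 and 3 (15 and 5, 15 and 2, and 13 and 3 adjusted over the list alone; adjusted p = 0.0028, 6.1e-06 and 0.00012), which also held with an estimated correlation, while the chemokine call was lost among genes above the median gene (adjusted p = 0.10). With the run term and M1 and M2a placed in different runs, 2129 genes changed; with only the M1 and M2a arrays in the fit, 10357 changed.

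Changes against M0 were also counted over both cytokine states. In both, 1448 genes rose and 1367 fell, against 747 and 426 for independent lists of the same sizes, while 309 rose in M1 and fell in M2a and 322 did the opposite, against 536 and 594. Simulated unchanged groups, with the M0 arrays drawn anew as well, gave 0 genes in each class on average. That count follows from the few calls of unchanged groups and does not bear on sharing. The covariance of the 2 sets of differences was 0.26, against 0.011 in the simulations, and their correlation across genes was 0.40, against 0.37. The simulations gave every group the same spread per gene and did not tie the M0 means. In the data the median SD of a gene was 0.24 in M0, 0.08 in M1 and 0.09 in M2a. The simulated values therefore do not show what the shared M0 arrays alone would give here. With the M0 arrays split in 20 ways, so that each state had M0 arrays of its own, the 4 counts were 927 to 2337, 1028 to 1873, 234 to 1026 and 258 to 975. The correlation was 0.26 to 0.40 with a median of 0.35, and its upper end is the split along the tie, whose 2 parts have the same mean. With the run term, which changes no difference, and both states placed with M0 arrays 4 and 5, 1326 genes changed the same way in both, against 2815 without it.

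**Figure D3:**
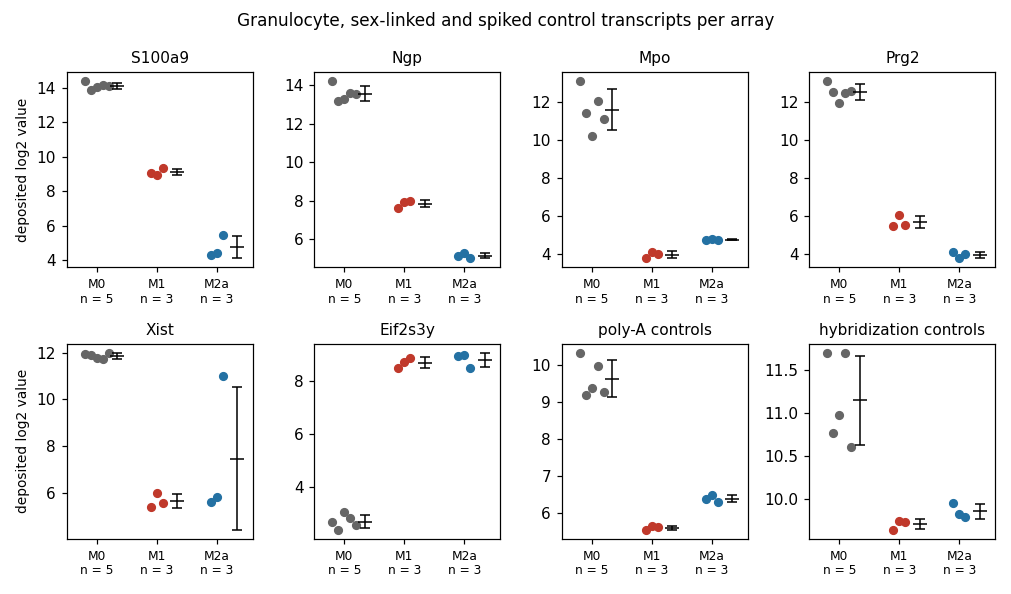
Deposited log2 values (vertical axis) of granulocyte genes, sex-linked genes and the means of spiked control probe sets in each array, by group (horizontal axis: M0, n = 5; M1, n = 3; M2a, n = 3). Points are arrays and black bars are mean ± SD; S100a9 averaged 14.11 in M0 and 4.75 in M2a, Xist of M2a array 3 lay 5.31 above the other M2a arrays, and the poly-A controls averaged 9.62 in M0, 5.62 in M1 and 6.40 in M2a.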

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

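The tests on sex-linked genes, on the tied M0 means, on the poly-A controls, on runs and on the share of macrophages were chosen after the values had been seen. Of the probe sets that the gene table does not list, 272 were at least 2-fold higher and 855 lower in M1 than in M0, and 117 were higher and 465 lower in M2a than in M0, a signal in data the report's comparisons do not use. A search of the M0 arrays for single arrays far from the others found none among 191 genes and control measures, but it could not have: the tied means held the ratio of gap to range at 0.667 or less for all 18193 genes, under the critical value of 0.71. That result says nothing about single M0 arrays.

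Most granulocyte-lineage transcripts were far higher in M0 than in M1 and M2a, with S100a9 at 14.11, Ngp at 13.57 and Prg2 at 12.53 in M0. Lcn2 was not lower in M1, at 12.62 to 12.68 beside 11.73 to 13.15 in M0. S100a8 stayed at 12.28 to 12.42 in M1, beside 13.65 to 14.08 in M0. Of 13 neutrophil-lineage genes, 4 were higher and 1 lower in M1 than in M2a (camera adjusted p = 0.024, and adjusted p = 0.68 with an estimated correlation). That call was lost in 9 of 30 alternatives. With the hybridization controls as a covariate, the neutrophil list stayed at a median of -4.81 in M2a against M0. That fit cannot exclude array-wide signal differences. The controls averaged 10.61 to 11.70 in the M0 arrays and 9.79 to 9.96 in the M2a arrays, without overlap. The covariate therefore goes together with the group, and its slope rests mostly on the M0 arrays. A candidate explanation is granulocyte and eosinophil precursors in the M0 sort, although sorting for F4/80 should remove neutrophil precursors (mouse eosinophils carry F4/80 and need not be removed); of a second granulocyte list, 10 of 18 measured genes, 55.6% against 7.51% of all genes, were lower in both states, between the bounds of 60% and 40% set beforehand, so this stays open (3 of its 26 genes are in other lists). A lower share of macrophages in the M0 sort also stays open. The NK, T and B list lay 6.46 above the neutrophil list, but its M0 level of 4.82 is under that of the median gene, 5.97. Rag1-/- mice also lack mature T and B cells. In M2a against M0, the neutrophil list had a median of -6.44. Medians of the mast cell and eosinophil, monocyte, stroma, erythroid and dendritic lists were -2.13, -1.73, -0.39, -0.14 and -0.03 over all measured members. Over members above the median gene in M0 they were -3.36, -2.18, -2.52, -1.60 and -0.04 (SDs of 1.22 to 3.22). The first values include members low in M0, and the second were picked by a high M0 value, which favours falls. Macrophages may also express these genes themselves, which was not tested, so neither set decides. Adgre1, which encodes F4/80, was higher than in M0 by 1.23 in M1 and 0.55 in M2a, the latter call lost in 14 of 30 alternatives. The macrophage identity list had medians of -0.14 and -0.22. An effect of the cytokines on the granulocyte-lineage transcripts was not tested. Whether precursors in the M0 sort also bear on the fall of the cell cycle genes in M1 and M2a was not tested either.

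Xist and Y-linked transcripts separated the groups: all 8 M0 and M1 arrays had opposite Xist and Eif2s3y levels, consistent with donors of one sex in M0 and of the other in M1. M2a replicates 1 and 2 had levels like those of M1 (Eif2s3y 8.94 and 8.96), so sex and cytokine state go together in these arrays. M2a replicate 3, the exception, had Ngp at 5.00 beside 5.11 and 5.27 and Mpo at 4.74 beside 4.75 and 4.79. These values go against sex as the source of the Ngp and Mpo differences from M0, but come from 1 array. Its Arg1, at 12.68 beside 13.08 and 13.13, cannot decide. Its Y-linked genes were at 57.7% to 72.2% of the other M2a arrays, so a gene high only in male samples would fall as little. That array had Xist 5.31 above the others, which had 5.58 and 5.81, and its 3 Y-linked genes averaged 0.61 less (-0.6113) than theirs, which differed by 0.14 from each other; this is consistent with pooled male and female donors. A swap of it with an M0 array is argued against, since its Eif2s3y was 8.48 and no M0 array exceeded 3.02. No biological explanation beyond sex was tested.

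The M0 arrays 1 to 3 and 4 and 5 had the same mean on every probe set. Chance is argued against: the median difference was 1.7e-06 and the largest 8.3e-05, spiked controls included, which is consistent with an adjustment that equalised M0 between 2 runs, though arrays calculated from the others would give the same tie. Poly-A controls were 0.78 higher in M2a than in M1, over 3 times the larger SD of 0.095, consistent with separate runs for the groups. Differences between runs as a source of the changes against M0 cannot be told apart from the cytokines, since the run of the M1 and M2a arrays is not given; the run terms, with 3256 as their lowest count, do not bear on this, since the tie sets them to 0 and they leave every difference as it was. No biological explanation was tested.

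Other splits of the arrays take the arrays as exchangeable, which the tie of the M0 means breaks. For M1 against M0, 1 of 56 splits, the real one, gave as many as 7217 genes, and the highest other gave 5359; for genes changed at least 2-fold the values were 2306 and 1269. For M2a against M0, 1 of 56 splits gave 5804 or more, with 4323 as the highest other, and 1703 against 811 for 2-fold changes. In 1 of 100 splits, the real one, 2815 genes changed the same way in both comparisons, and the highest other gave 34. Because of the tie, these splits alone do not exclude chance. The 10 splits of M1 against M2a are too few for a share under 0.05; the real split, 1 of the 10, gave 5341 genes and 1998 changed at least 2-fold, and the highest other gave 0 and 0.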

How the results depend on the processing

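The run terms, the control-probe covariates, the weights by group and the fit without M0 arrays 1 and 4 were chosen after the data were seen. Leaving out 1 array at a time gave 5391 to 8457 genes in M1 against M0, 4161 to 6829 in M2a against M0 and 3927 to 6192 in M1 against M2a; at least 2-fold, 2114 to 2620, 1562 to 1868 and 1893 to 2024; and 2008 to 3762 genes changed the same way in both comparisons against M0. Testing each probe set, which tests more features, gave 17989, 13716 and 12667 probe sets, and 5628, 3739 and 4539 at least 2-fold. Only genes above the median gene gave 4625 in M1 against M0, with fewer genes tested. For M1 against M2a, fitting only these groups gave 10357, array weights 11342, weights by group 10384, leaving out M0 arrays 1 and 4 8653 and the hybridization covariate 8442; these settings take out or weigh down the M0 arrays, with the larger spread, except the covariate, for which the cause was not tested. That covariate gave 9008 genes and 2705 at least 2-fold in M2a against M0, and 5504 shared; array weights gave 4495 shared. The run terms, which the tie sets to 0, leave every difference as it was and lower the counts through fewer degrees of freedom and fewer M0 arrays per run; they gave 4389 in M1 and 3256 in M2a against M0 where that group was placed with M0 arrays 4 and 5, 2129 in M1 against M2a where they were placed apart, and 1790, 1326, 1484 and 1576 shared for both with arrays 1 to 3, both with 4 and 5, M1 with 1 to 3 and M1 with 4 and 5. Centring arrays on their medians moved the median gene of M1 against M0 from 0.06 to 0.11.

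With the replicate number as a block (replicate block), 8023, 6492 and 6963 genes changed, and 3355 were shared. Same-numbered arrays had correlations of deviations of -0.039 to 0.25 in 9 pairs, 2 of them over 0.1. Differently numbered arrays reached -0.34 and 0.34. The deviations within a group depend on each other, so these correlations do not show whether the numbers pair the arrays. Of the list results under the alternatives, 2423 kept direction and side of the threshold, 55 lost and 35 gained a call and 4 reversed; of the named genes these were 7404, 343, 27 and 22. The run terms are counted in these tallies although they cannot change a direction, and all 84 list results stayed the same under each of them. For the reversals the cause was not tested. With the mean of a gene's probe sets, Fscn1, Pdgfra and Pdgfrb were -0.44, -0.054 and -0.050 in M1 and Pdgfra -0.39 in M2a against M0; without _x_at and _s_at probe sets, Irak1 was 0.057 in M1 and Slc2a3 0.23 in M2a. With the actin covariate the TCA list was 0.026 by its median, its test reversed, and Idh3a -0.26 in M1. With the hybridization covariate, in M1 the TCA list was -0.34, Acsl4 -0.78, Cd36 -0.72 and Idh3a -0.95; in M2a the TCA list was -0.087, the fatty acid list -0.56, Acsl4 -0.27, Adgre1 -0.32, Ccl22 0.45, Ccnd1 -0.15, Cxcl14 -0.35, Erap1 -0.54, Gbp2 -0.37, Mrc1 -1.32, Ms4a1 0.35, Rel -0.21, Trem2 -0.31 and Usp18 -0.11. No background or detection values were used here, so it is not known which low values lie above background. The planned transformation of linear values with another added constant gave no result, since the values are already log2.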

Other observations

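The lists below were chosen after the data had been seen and are described, not offered as findings. In M2a against M0, 16 of 19 genes of the response to the stress-induced factor Atf4 rose and none fell (16 adjusted over the list alone; median 1.46, camera adjusted p = 3.0e-09, and adjusted p = 0.036 with an estimated correlation). Trib3 rose by 3.62, Cth by 2.53, Phgdh, of serine synthesis, by 2.13 and Asns, asparagine synthetase, by 2.04. Over the alternatives, the rise of Trib3 was 2.23 to 3.79. In M1 against M0, 4 of the 19 rose and 10 fell (4 and 11 adjusted over the list alone; adjusted p = 0.037, and adjusted p = 0.39 with an estimated correlation). Psat1 fell by 2.57, while Nupr1 rose by 4.25.

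Of 17 genes of cell fusion and osteoclasts, 10 rose and 2 fell in M2a against M0 (10 and 3 adjusted over the list alone; adjusted p = 0.0027, and adjusted p = 0.036 with an estimated correlation). The fusion genes Ocstamp and Dcstamp rose by 3.10 and 2.96, Cdh1, E-cadherin, by 3.10 and Car2 by 3.01. In M1 against M0, 4 rose and 6 fell (4 and 8 adjusted over the list alone; adjusted p = 0.037, and adjusted p = 0.19 with an estimated correlation). Of 13 heat shock genes, 11 rose in M1 (11 adjusted over the list alone; adjusted p = 6.1e-05, and adjusted p = 0.23 with an estimated correlation) and 7 rose and 1 fell in M2a (7 and 1 adjusted over the list alone; adjusted p = 0.026, and adjusted p = 0.46 with an estimated correlation). The 16 prostaglandin and leukotriene genes moved both ways, with adjusted p = 0.93 in M1 and 0.25 in M2a against M0. Within M0, array 1 had the highest value for 11 of the 13 neutrophil-lineage genes.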
